A study of Mus musculus with 8 samples.

How the data were processed

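Chromatin was profiled by FAIRE and by LRH-1 ChIP before and 4 h after hCG, and RNA was profiled in CTL and cKO granulosa cells at both times. Per the labels' protocols, FAIRE and RNA material came from granulosa cells released by puncture of the ovary, RNA libraries started from 300 ng, and the LRH-1 ChIP started from ovarian tissue (n = 5 per condition) fixed with 1.1% formaldehyde and used 10 µg of antibody. The ChIP peaks can therefore hold sites of other ovarian cells.

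Per the submitters' processing notes, reads of FAIRE and ChIP were aligned with BWA to mm9, ChIP peaks were called with MACS2 2.1.0 and handled with bedtools, and RNA reads went through Trimmomatic, TopHat2 2.0.12, kallisto and DESeq2, with no role or order given. The peak caller for FAIRE is not given in the sources used here. The deposited FAIRE lists give a position and a score per peak, no score is below 40, and peak numbers in the names run past the number of rows (22006 for 21431 peaks before hCG and 23412 for 22791 after it), so some numbered peaks are not in the lists. The deposited LRH-1 lists give per peak a score, a fold enrichment ratio, the −log10 of the p-value, the −log10 of the q-value and the summit. Each label states 2 replicates and each time has 1 list; whether replicates were pooled before peak calling is not given in the sources used here. The deposited kallisto tables give, per the file headers, estimated counts, TPM and the length and effective length of each transcript, in 3 tables per group; the number of each library is known only from its file. Lists and tables name no build, so mm9 rests on the processing notes; in 10 of 20 chromosomes the last peak lies beyond the last gene of the GRCm38 table, which argues against that build.

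RNA was tested per transcript, as planned for the case that transcripts cannot be matched to genes: identifiers are of transcripts, and the tables of gene names used here hold gene identifiers and RefSeq accessions only. Gene lists, cell type markers, the check of Nr5a2 and links from peaks to genes were not run, and the motif test was not run because no mm9 sequence was used here. Estimated counts were rounded to whole numbers. In R 4.3.3, edgeR 4.0.16 kept 32944 of 110473 transcripts with filterByExpr (95.9% of all counts), scaled by TMM, fitted all 12 libraries in 1 model of 4 groups and tested 5 contrasts with glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are rounded counts scaled to an equal library total. Detected transcripts are the expected number with at least 1 read after thinning each library to the smallest total, and the effective number is a diversity measure of the counts over transcripts. Library measures were tested by permuting the time labels within genotype, or the genotype labels within time, over all 400 arrangements. Named transcripts had to pass the threshold, with libraries of the groups that do not overlap (for the interaction, without this condition) and a mean of at least 5 CPM in the highest group, up to 8 per direction. With no names, at most 2 that rose and 2 that fell are printed. All 11 interaction calls met the rule, and the 3 printed were chosen after their values were seen. In the comparisons of 2 groups, ENSMUST00000061352, ENSMUST00000108759 and the hCG change of ENSMUST00000055820 fall outside the rule and were chosen after their values were seen. For peaks, the 3 best-scoring of each list and the 3 best-scoring of a single time were named. FAIRE peaks were ranked by their listed score. LRH-1 peaks were ranked by the −log10 of the q-value, which is called their score in all that follows.

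Peaks were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks overlap if they share at least 1 bp. Chance overlap came from 1000 circular shifts within each chromosome, and Fisher's exact test compared gained or lost LRH-1 peaks with those present at both times. Intervals of shares are exact (Clopper-Pearson) at 95%, and those of the Mantel-Haenszel odds ratio are by Robins, Breslow and Greenland. Intervals of the odds ratios for FAIRE peaks near LRH-1 peaks are conditional exact ones, printed beside the sample odds ratio. Printed starts count from 1. The FAIRE midpoint was used where no summit is given.

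Alternatives were other scaling factors, filters and lengths as an offset, a fold threshold, a replicate block, fits on 2 groups, DESeq2 1.42.0, limma 3.58.1 on log2(TPM + 1), each library left out in turn, other overlap rules and stricter or equal peak numbers. Filters on mean CPM, a robust fit, and leaving out or modelling the 3 libraries that stand apart were added after the data were seen. Counts per library, at 9250965 to 23753060 estimated counts, set the counting error of RNA values but not the spread between libraries. Read depths of the peak lists are not in the sources used here. The tests were checked on simulated counts with 200 changed transcripts. At a coefficient of variation of 0.4, edgeR recovered 98.2% of 16-fold changes for cKO against CTL after hCG, 100% before hCG, 98.5% for hCG in CTL, 95.1% for hCG in cKO and 96.5% for the interaction, over 32944 transcripts each. The overlap code found all 1000 peaks placed inside FAIRE peaks and 0 of 1000 placed outside.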

Results

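The series followed mouse granulosa cells, the somatic cells that surround the oocyte, or ovarian tissue that holds them, across the ovulatory signal, and asked where the nuclear receptor LRH-1 (NR5A2) was bound, which chromatin was open and which transcripts depended on LRH-1 before and after that signal. Mice aged 22 to 25 days received 5 IU of equine chorionic gonadotropin (eCG), which drives follicle growth, and 44 h later 5 IU of human chorionic gonadotropin (hCG), which stands in for the luteinising hormone surge. Samples were taken at 0 h (before hCG) or at 4 h after hCG, as granulosa cells for FAIRE and RNA and, per the labels' protocol, as ovarian tissue for LRH-1 binding. Open chromatin was measured by FAIRE (formaldehyde-assisted isolation of regulatory elements) and LRH-1 binding by chromatin immunoprecipitation (ChIP), each with 1 deposited peak list per time although the labels state 2 replicates. RNA was measured in control mice (CTL) and in mice in which Amhr2-Cre had removed floxed Nr5a2 from granulosa cells (cKO), at both times, with 3 libraries in each of 4 groups. The 12 RNA libraries covered 110473 transcripts. Their totals of estimated counts ran from 9250965 to 15439164 in CTL and from 12867403 to 18022984 in cKO before hCG, and from 12517554 to 18286964 in CTL and from 16721397 to 23753060 in cKO after it. Nothing in the labels says that replicates came from separate animals or pools, so the p-values measure the spread between these libraries. All peak positions are in mouse build mm9.

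The first comparison asked how open chromatin changed within 4 h of hCG. The FAIRE lists held 21431 peaks before and 22791 peaks after hCG, with median widths of 918 and 897 bp. Of the peaks before hCG, 11521 (53.8%, exact binomial 95% confidence interval 53.1 to 54.4) overlapped a peak after hCG by at least 1 bp, against a mean of 1.71% and a maximum of 2.03% when the peaks were moved by 1000 random circular shifts within each chromosome (one-sided permutation p = 0.001, the smallest these shifts can give). Of the peaks after hCG, 11535 (50.6%) overlapped a peak before hCG. That left 9910 FAIRE peaks seen only before hCG and 11256 seen only after it. The best-scoring peak of both lists lay on chromosome 5, from 60433426 to 60434848 before hCG and from 60433534 to 60434486 after it, with authors' scores of 2340 and 1490. The next best before hCG lay on chromosome 17 at 57170751 to 57171972 and at 56218077 to 56219216, and the next best after hCG on chromosome 8 at 4165746 to 4166606 and on chromosome 7 at 134352060 to 134353096. All of them were present at both times. None overlapped a LRH-1 peak at either time, except that from 56218077 to 56219216 on chromosome 17, which overlapped one after hCG only. The best-scoring peaks without a counterpart after hCG were a pair on chromosome 13, at 16546119 to 16547593 (score 458) and 16433288 to 16434888 (score 357), and 1 on chromosome 1 at 81893200 to 81894279 (score 307). All 3 overlapped LRH-1 peaks at both times. The best-scoring peaks without a counterpart before hCG lay on chromosome 3 at 101171060 to 101172027 (score 467), on chromosome 4 at 64903342 to 64904400 (score 438) and on chromosome 18 at 70747137 to 70748343 (score 437), and the one on chromosome 3 overlapped a LRH-1 peak after hCG. Scores are the authors' own values for each peak (for LRH-1 peaks below, the −log10 of the q-value) and rank peaks within a list only. Peak lists have no replicates here, so shares and tests on peaks compare these lists, and the intervals cover counting error only. The circular shifts here and below placed peaks anywhere within the span of a chromosome, without regard to where peaks can occur. Lists of other regulatory sites may also reach the smallest p against them.

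The second comparison asked whether LRH-1 changed its sites after the ovulatory signal. The LRH-1 list grew from 5886 peaks before hCG to 9413 after it, and the median authors' fold enrichment was 5.75 and 5.31. Of the peaks before hCG, 3938 (66.9%, 95% interval 65.7 to 68.1) overlapped a peak after hCG, against a mean of 0.257% and a maximum of 0.459% under circular shifts (one-sided permutation p = 0.001, the smallest possible). Of the peaks after hCG, 3940 (41.9%) overlapped a peak before hCG. Accordingly 1948 LRH-1 peaks were seen only before hCG (called lost below) and 5473 only after it (called gained). Where a peak was present at both times, its summits lay a median of 44 bp apart. The best-scoring LRH-1 peak at both times was on chromosome X, at 73399408 to 73399826 before hCG and 73399394 to 73399840 after it, with 30.1-fold enrichment in each list and no FAIRE peak at either time. The next best-scoring before hCG lay on chromosome 1 at 65087375 to 65087768 and on chromosome 11 at 53953531 to 53954257, each 18.6-fold enriched, and both overlapped FAIRE peaks at both times. The next best-scoring after hCG lay on chromosome 12 at 80599949 to 80600395 (20.9-fold), with a FAIRE peak only after hCG, and on chromosome 1 at 184430980 to 184431459 (18.7-fold), with none. The best-scoring lost peaks were on chromosome 9 at 40250385 to 40250733 (13.1-fold), chromosome 1 at 137101992 to 137102408 (14.5-fold) and chromosome 3 at 52617444 to 52617816 (11-fold), and none overlapped a FAIRE peak. The best-scoring gained peaks were on chromosome 15 at 52759823 to 52760361 (11.3-fold), on chromosome X at 101211463 to 101211834 (9.99-fold) and on chromosome 17 at 35913891 to 35914304 (10.1-fold). The peaks on chromosomes 15 and 17 each overlapped a FAIRE peak present only after hCG.

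Peaks with better scores were more often shared between times in every list. Among LRH-1 peaks before hCG, 94.1% of the best-scoring 589 peaks were found again after hCG, against 49.1% of the worst-scoring 589. Among LRH-1 peaks after hCG, 87.6% of the best-scoring 942 had been present before, against 15.8% of the worst-scoring 942. The FAIRE list before hCG ran from 26.7% in its worst-scoring 2144 peaks to 96.2% in its best-scoring 2143, and the list after hCG from 32.1% to 80.9%. The best 5886 LRH-1 peaks of each time shared 53.8% of the peaks before hCG and 53.7% of those after it.

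**Figure D1:**
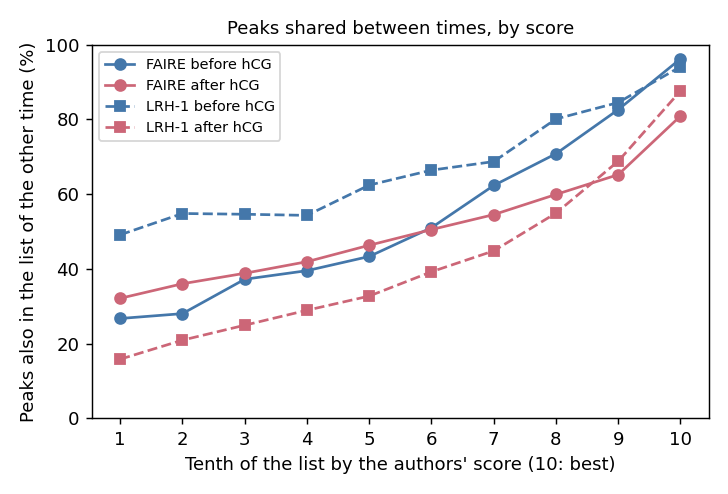
Percent of peaks also found in the list of the other time (vertical axis) for peaks in 10 equal groups by the authors' score within each list (horizontal axis, 10 is best), for FAIRE (circles) and LRH-1 (squares) before and after hCG. The score of LRH-1 peaks is the −log10 of the q-value. In the LRH-1 list after hCG the share runs from 15.8% to 87.6%.

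The third comparison asked whether LRH-1, measured in ovarian tissue, sat in chromatin that was open in granulosa cells at each time. Before hCG, 3159 of 5886 LRH-1 peaks (53.7%, 95% interval 52.4 to 55) overlapped a FAIRE peak of the same time, against a mean of 1.1% under circular shifts (one-sided permutation p = 0.001, the smallest possible). After hCG, 3913 of 9413 did (41.6%, 95% interval 40.6 to 42.6), against a mean of 1.18% (same p). Set against the FAIRE list of the other time, the shares were 34.6% for LRH-1 peaks before hCG and 38.3% for those after it. Of LRH-1 peaks before hCG, 1506 overlapped only the FAIRE list of the same time and 386 only that of the other time (exact binomial p = 8.82e-156, two-sided); after hCG the numbers were 1593 and 1288 (p = 1.44e-08). Seen from the FAIRE peaks, 14.6% of those before hCG and 16.9% of those after it held a LRH-1 peak of the same time. Before hCG this share was 14.5% for FAIRE peaks that persisted and 14.7% for those that did not (Fisher's exact p = 0.816, two-sided). After hCG it was 20.2% for FAIRE peaks already present before and 13.5% for those seen only after hCG (odds ratio 1.61, Fisher's exact p = 5.04e-41). FAIRE peaks of both times had the higher scores, with medians of 93.8 against 57 before hCG and 85.7 against 61.2 after it. Of 10 equal groups by FAIRE score, the worst-scoring held LRH-1 at 7.88% of peaks before hCG and 8.68% after it. The share was highest in the group next to the best-scoring, at 24.7% and 27.6%, and lower in the best-scoring, at 19.8% and 23.7%. Within 10 equal groups by FAIRE score, a comparison added after the data were seen, the Mantel-Haenszel odds ratio for peaks of both times against those of a single time was 0.616 before hCG (95% interval 0.565 to 0.672) and 1.32 after it (95% interval 1.22 to 1.42).

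The fourth comparison asked whether gains and losses of LRH-1 went with gains and losses of open chromatin. A LRH-1 peak was counted at a FAIRE peak seen only after hCG if it overlapped the FAIRE list after hCG and not that before it. The reverse held for those seen only before hCG. Some of these FAIRE peaks can still overlap a FAIRE peak of the other time outside the LRH-1 peak. Of the 5473 gained LRH-1 peaks, 1266 (23.1%, 95% interval 22 to 24.3) lay at FAIRE peaks seen only after hCG, against 327 of 3940 LRH-1 peaks present at both times (8.3%, 95% interval 7.46 to 9.2; odds ratio 3.32, Fisher's exact p = 1.49e-85, two-sided). Of the 1948 lost LRH-1 peaks, 633 (32.5%, 95% interval 30.4 to 34.6) lay at FAIRE peaks seen only before hCG, against 873 of 3938 present at both times (22.2%, 95% interval 20.9 to 23.5; odds ratio 1.69, Fisher's exact p = 3.34e-17). The opposite pairing was rarer: 415 gained peaks (7.58%) lay at FAIRE peaks seen only before hCG, and 60 lost peaks (3.08%) at FAIRE peaks seen only after it. Among peaks at FAIRE sites of a single time, the ratio of after-only to before-only FAIRE sites was 3.05 for gained, 0.375 for persistent and 0.0948 for lost LRH-1 peaks (gained against lost: odds ratio 32.2, Fisher's exact p = 1.04e-212). Of the remainder, 2844 gained peaks (52%) and 971 lost peaks (49.8%) had no FAIRE peak at either time, compared with 1368 of the persistent ones (34.7%), and 948 gained (17.3%) and 284 lost peaks (14.6%) lay at FAIRE peaks of both times. The gained share of the LRH-1 peaks after hCG ran from 51.4% on chromosome 14 to 61.7% on chromosome 17. The window of 1 Mb with the most gained peaks, on chromosome 4 from 129000001 to 130000000, held 21 gained, 2 lost and 3 persistent LRH-1 peaks, with 17 FAIRE peaks seen only after and 7 seen only before hCG. Of the windows with the most lost peaks, 3 on chromosomes 7, 11 and 15 held 10, 6 and 6 lost and 8, 15 and 8 gained peaks. Their after-only and before-only FAIRE peaks numbered 12 and 15, 16 and 10, and 23 and 12.

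**Figure D2:**
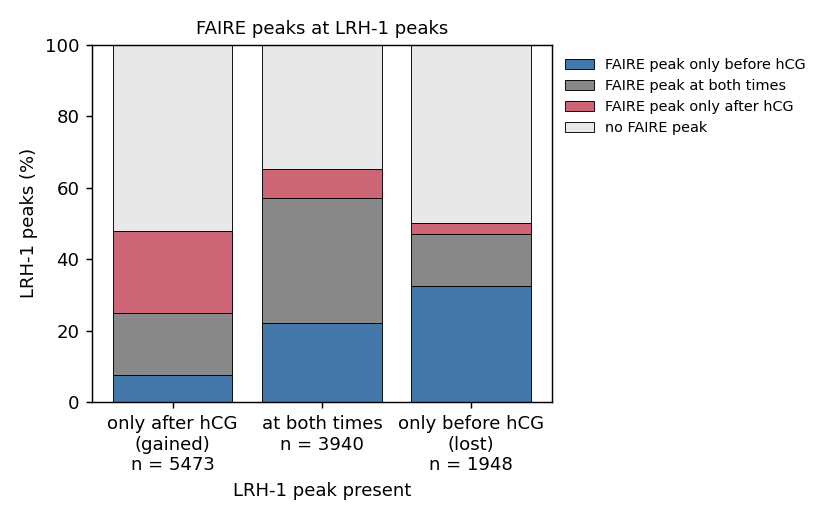
Percent of LRH-1 peaks (vertical axis) by the FAIRE peaks they overlap, for LRH-1 peaks seen only after hCG (n = 5473), at both times (n = 3940) and only before hCG (n = 1948). Overlap with the FAIRE list after hCG and not that before it holds for 23.1% of gained, 8.3% of persistent and 3.08% of lost LRH-1 peaks.

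The RNA libraries were compared as wholes before single transcripts. After hCG, fewer transcripts were detected over both genotypes when every library was thinned to the depth of the shallowest. CTL libraries held 27712 ± 4633 transcripts before hCG (SD, n = 3) and 18892 ± 7837 after it, and cKO libraries 31887 ± 5986 and 16262 ± 1048. Over both genotypes the means were 29800 before and 17577 after hCG (exact stratified permutation p = 0.015, two-sided, 6 libraries a side, adjusted p = 0.04 over 8 tests of 4 measures, smallest possible p 0.005). Without the 3 libraries that stand apart, described below, the mean difference was -13528 (exact permutation p = 0.0333); those 3 held 24602 and 31155 transcripts before hCG and 20273 after it. The effective number of transcripts fell from 4820 to 2384 (exact permutation p = 0.01, adjusted p = 0.04), and the mean transcript length weighted by counts fell from 3852 to 3426 bases (exact permutation p = 0.005, adjusted p = 0.04). The share of counts in the 100 most abundant transcripts was 23.1% before and 30% after hCG (exact permutation p = 0.04, adjusted p = 0.08). None of the 4 measures differed by genotype past the threshold, with 23302 transcripts in CTL and 24074 in cKO (exact permutation p = 0.81, adjusted p = 0.91). In the single genotypes, 3 libraries against 3 cannot give a p under 0.1. In cKO the libraries of both times did not overlap in detected transcripts (exact permutation p = 0.1). In CTL they did, as replicate 3 after hCG held 25947 transcripts and replicates 1 and 2 before it 24602 and 25497 (exact permutation p = 0.3). The CTL difference of -8819 was -4602 without replicate 2 after hCG, which held 10457.

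**Figure D3:**
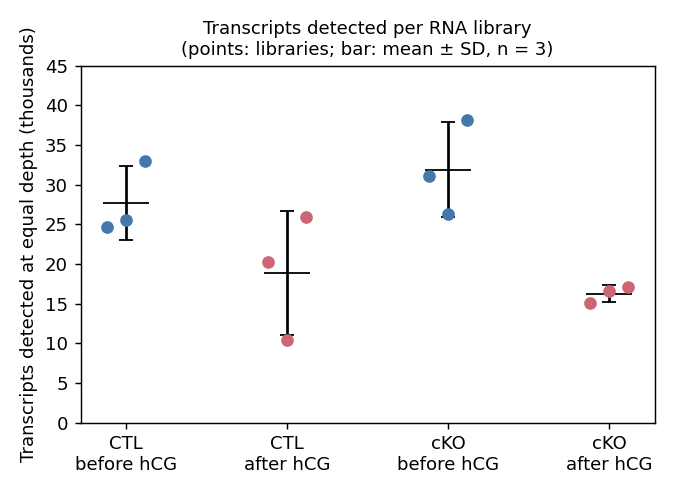
Transcripts with at least 1 read after thinning to equal depth, in units of 1000 (vertical axis), for the 3 libraries of each RNA group (points), with mean ± SD. The cKO libraries after hCG average 16262 and those before hCG 31887.

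Libraries of the same group resembled each other weakly. Over the 14053 transcripts with a mean of at least 10 CPM (counts scaled to an equal library total), Pearson's r between libraries of a group had a median of 0.26 (range 0.21 to 0.48, 12 pairs), and the median over all 66 pairs was 0.25. Transcripts are not independent replicates. Pairs of libraries from the same group shared a median of 38.5 of their 100 most abundant transcripts, and pairs from other groups 36. Time nevertheless separated the libraries on the first principal component (17.6% of the variance), where those before hCG lay between -327 and -109 and those after it between -10.7 and 471 (exact permutation p = 0.005, the smallest possible). This component was close to the order of detected transcripts, from 471 for the library with 10457 to -327 for that with 38205, so it adds no evidence apart from the fall in detection. Libraries of the same time correlated better than those of different times, by 0.057 in r (exact one-sided permutation p = 0.02, adjusted p = 0.04 over 2 tests), while the same difference for genotype was -0.0161 (exact one-sided permutation p = 0.57). The hCG changes in CTL and in cKO, which share no library, correlated across transcripts with r = 0.254 and Spearman's rho = 0.25 (exact one-sided permutation p = 0.01, 2 of 200 arrangements, adjusted p = 0.02 over 2 relations). The highest r of another arrangement was 0.298. The cKO effects before and after hCG did not, with r = 0.0297 (p = 0.26 by the same permutation). Transcripts that drop out of detection after hCG in both genotypes can raise the r of 0.254 and the difference of 0.057 by themselves. Neither is therefore evidence apart from the fall in detection. Replicate 1 of CTL before hCG, of CTL after hCG and of cKO before hCG stood apart on the second component and correlated among themselves with a median r of 0.4.

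**Figure D4:**
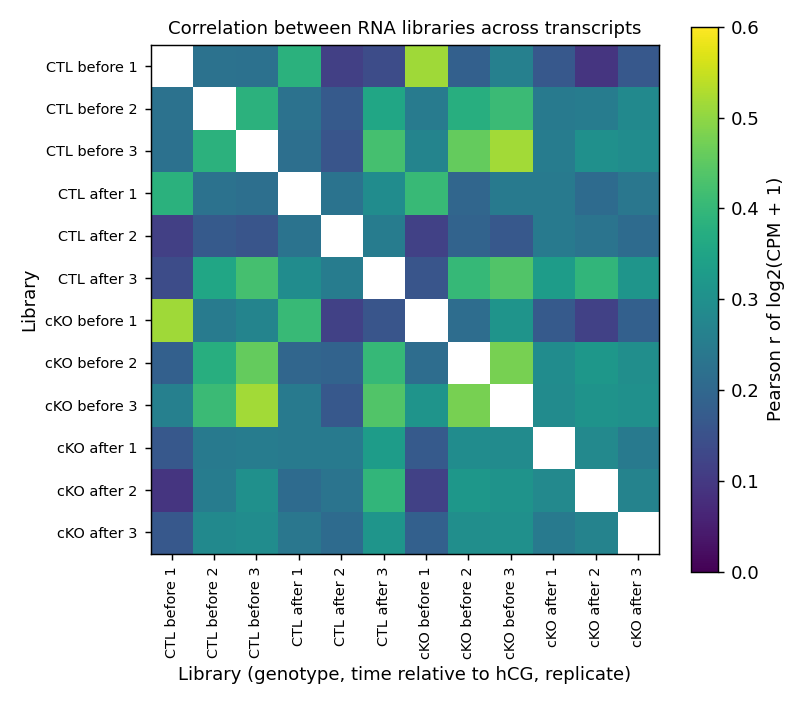
Pearson's r of log2(CPM + 1) across 14053 transcripts for each pair of the 12 RNA libraries, by genotype, time relative to hCG and replicate (both axes). The highest value, 0.52, joins libraries of the same time and replicate number but different genotype.

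The effect of losing LRH-1 was tested per transcript, because the estimated counts carry transcript identifiers and no table used here pairs these with gene names. Nr5a2 itself was therefore not checked in the cKO libraries. Before hCG, edgeR's quasi-likelihood test called 2 of 32944 transcripts higher in cKO than in CTL and 0 lower (Benjamini-Hochberg adjusted p under the threshold). The clearer one, ENSMUST00000055820 (638 bases), stood at 13.8 ± 23.6 CPM in CTL and 2160 ± 1920 CPM in cKO (SD, n = 3), 156-fold higher, with every cKO library above every CTL library (edgeR adjusted p = 0.00464). The fold was at least 7030 without CTL replicate 1, which held 41.1 CPM, 105 and 104 without CTL replicates 2 and 3, and 75.8 without cKO replicate 2, which held 4380 CPM. The call was lost without CTL replicate 2 (adjusted p = 0.628), CTL replicate 3 (adjusted p = 0.594) or cKO replicate 2 (adjusted p = 0.228), and the count of calls was 0 without any 1 of these and 1 without CTL replicate 1 or cKO replicate 3. ENSMUST00000055820 did not separate the genotypes after hCG, at 0, 1490 and 1510 CPM in CTL and 13600, 0 and 1350 CPM in cKO. After hCG, edgeR called 1 transcript higher and 2 lower in cKO. This balance did not hold in other fits, as the replicate number as a block gave 4 higher and 0 lower and a term for the 3 libraries that stand apart 4 higher and 1 lower, with 0 of the 3 main calls among either. ENSMUST00000061352 (1502 bases) was 795 ± 1370 CPM in CTL and at 0 in the 3 cKO libraries, at least 5390-fold lower against a floor of 3 counts per library (edgeR adjusted p = 0.0213), but 2380 CPM in replicate 1 made up most of the CTL mean and replicate 2 was also at 0. Over all 12 libraries it followed the 3 that stand apart, at 498 CPM in replicate 1 of CTL before hCG, 2380 CPM in that after hCG and 804 CPM in replicate 1 of cKO before hCG, with 7.03 CPM in replicate 3 of CTL after hCG and 0 in the other 8; none of the 3 is a cKO library after hCG. Without those 3 libraries edgeR called 0 transcripts after hCG. The call was lost without CTL replicate 1 (adjusted p = 0.433, at least 23.8-fold) or without cKO replicate 1, 2 or 3 (adjusted p = 0.109, 0.108 and 0.124). The count of calls was 0 without CTL replicate 1 or cKO replicate 1, 1 without cKO replicate 2 or 3, and 7 without CTL replicate 2 or 3. At an unadjusted p under 0.05 the same test had 2199 transcripts before and 5599 after hCG, where the other 9 splits of the same 6 libraries into 3 against 3 gave 2066 to 3257 and 5336 to 6329. DESeq2 called 1028 and 3877. Transcripts whose CTL and cKO libraries did not overlap numbered 2100 (6.37%) before and 1445 (4.39%) after hCG. Chance gives 10% where no values are tied, but libraries tied at 0 lower this, and the other splits gave a median of 3152 (1775 to 3975) before and 1598 (1152 to 2222) after hCG.

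The response to hCG was tested in each genotype. In CTL, edgeR called 1 transcript higher and 1 lower after hCG. The replicate block gave 4 higher and 3 lower and the term for the 3 libraries that stand apart 8 higher and 3 lower, both main calls among them. ENSMUST00000055820 was 72.3-fold higher at 1000 ± 867 CPM after hCG (adjusted p = 0.0335), although replicate 1 after hCG was at 0. The fold ran from 48.2 without replicate 3 before hCG and 48.8 without replicate 2 to at least 3260 without replicate 1 before hCG, and the call was lost without replicate 2 or 3 before hCG or replicate 2 after it (adjusted p = 0.481, 0.485 and 0.1). ENSMUST00000108759 (2309 bases) was 1150 ± 1320 CPM before hCG and at 0 in the 3 CTL libraries after it, at least 5840-fold lower against a floor of 3 counts per library (adjusted p = 0.0335), although replicate 1 before hCG was at 0 too, and the call held only without that replicate (adjusted p = 0.0196) and lay between 0.131 and 0.481 without any 1 of the other 5 libraries. Without replicate 2 before hCG, at 2590 CPM, it was at least 2190-fold lower, and without replicate 1 at least 8770-fold. The count in CTL was 0 without replicate 2 or 3 before hCG or replicate 2 after it, 1 without replicate 1 after it and 5 without replicate 3 after it. In cKO, edgeR called 0 transcripts (1 without replicate 2 or 3 after hCG, 8 with the replicate number as a block, all higher, and 12 with a term for the 3 libraries that stand apart, 9 higher and 3 lower), with 6135 at an unadjusted p under 0.05, and DESeq2 called 4137; in CTL these numbers were 4835 and 3099. The other 9 splits of the 6 libraries gave 2622 to 3734 transcripts at that p in cKO and 3266 to 5674 in CTL. Non-overlapping libraries were found for 3170 transcripts (9.62%) in CTL, of which 2666 were lower after hCG, and for 5736 (17.4%) in cKO, of which 5431 were lower and 305 higher. Beside the 10% of chance without ties, the other splits gave a median of 1990 (1413 to 3696) in CTL and 1907 (1261 to 2825) in cKO. At equal depth, detected transcripts averaged 31887 before and 16262 after hCG in cKO, and 27712 and 18892 in CTL. The larger counts in cKO, mostly of lower transcripts, can follow from this fall in detection. They do not show a larger response to hCG without LRH-1.

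Whether the hCG response depended on LRH-1 was tested as the interaction of genotype and time. edgeR called 11 transcripts, 7 with a more positive hCG response in cKO and 4 with a more negative one, with 4397 at an unadjusted p under 0.05, and DESeq2 called 3493. ENSMUST00000211290 (3035 bases) had the smallest share of its counts in a single library, at 34.2%, against 57.7% to 97.5% for the other interaction calls. In CTL it was 266 ± 115 CPM before and 18.8 ± 31.6 CPM after hCG, and in cKO 0.0195 ± 0.0337 before and 305 ± 235 CPM after it, and in each genotype the libraries of both times did not overlap (edgeR adjusted p = 0.0413, lost in 11 of 12 fits without 1 library, all but that without CTL replicate 3 after hCG, at up to 0.417 without cKO replicate 1 before hCG). Leaving out 1 library gave 1 call (without cKO replicate 3 before hCG) to 13 (without CTL replicate 2 after hCG). Regrouping the genotypes at random within each time gave at least 11 interaction calls in 40 of 40 arrangements, the real one included, and at least 4397 transcripts at an unadjusted p under 0.05 in 31 of 40. The common biological coefficient of variation was 2.43. Simulated tables of the 32944 transcripts gave each its own estimated spread (median coefficient 2.64). In them edgeR recovered 0% of transcripts changed 64-fold in each of the 5 comparisons. DESeq2, run on 8388 transcripts for cKO against CTL before hCG, recovered 18.8% but also called 282 unchanged transcripts. For the interaction edgeR called 0 unchanged transcripts in these tables, where the other arrangements of the real labels gave 11 to 186 calls. The simulated tables thus do not behave like the real libraries and do not give the power of these tests.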

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

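The tests of depth, abundant transcripts, RNA breakage, the shared hCG response, groups at 0, peak strength, list thresholds and the splits of the libraries were set out only after the results were seen; the test of open chromatin in the LRH-1 assay was set out before its result.

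The edgeR interaction test called a different hCG response in CTL and cKO for 11 transcripts. Among them were ENSMUST00000211290 (adjusted p = 0.0413), ENSMUST00000108759 (adjusted p = 0.00697) and ENSMUST00000061352 (adjusted p = 0.0139). These calls were lost in 11, 7 and 7 of the 12 fits without 1 library. ENSMUST00000108759 had 73.1% of its counts in 1 library, replicate 2 of CTL before hCG. The counts of ENSMUST00000061352 lay in the 3 libraries that stand apart (498, 2380 and 804 CPM, against 0 to 7.03 CPM in the others), so its call follows those libraries and is no evidence of a genotype difference. Chance cannot be excluded for the count, because 40 of 40 arrangements of the genotype labels within each time gave 11 calls or more. The highest other count was 186. Structure of the samples and counts carried by 1 library were not told apart as its source. With a term for the 3 libraries that stand apart, 32 of 40 arrangements gave the real count of 8 calls or more and the highest other count was 27. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real edgeR count was 2 with a highest other of 9 for cKO against CTL before hCG (5 of 10 splits as large), 3 with a highest other of 10 after hCG (10 of 10), 2 with a highest other of 15 for hCG in CTL (5 of 10), and 0 with a highest other of 3 for hCG in cKO (10 of 10).

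DESeq2 called 1028 to 4137 transcripts in comparisons where edgeR called at most 11. At least 83.7% of the DESeq2 calls in each of the 4 comparisons of 2 groups had a whole group at 0, against 10.1% to 30.6% of all transcripts tested. Of the same calls 93.3% to 99% had most of their counts in 1 of the 6 libraries, against 65.7% to 80.7% of all tested. In simulated counts with the spread found here and 200 changed transcripts, DESeq2 called 282 unchanged transcripts out of 8388 tested for cKO against CTL before hCG. Whether those false calls had a group at 0 was not recorded, so they show only that DESeq2 makes false calls at this spread. By the shares in the real calls, transcripts listed at 0 in 3 libraries are a candidate source of the gap. Counts carried by 1 library are not separated from it. On 5491 transcripts, every 6th of those tested, the real DESeq2 count was 182 for cKO against CTL before hCG (6 of 10 splits as large, highest other 256), 620 after hCG (8 of 10, highest other 718), 564 for hCG in CTL (2 of 10, highest other 593) and 680 for hCG in cKO (1 of 10, highest other 394). These splits are again too few for a share under 0.05. No biological explanation was tested.

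Fewer transcripts were detected after hCG over both genotypes, with libraries of both times apart in cKO and overlapping in CTL (exact permutation p = 0.1, the smallest possible, and 0.3). Depth is argued against, since the difference was -12223 transcripts at equal depth and the libraries after hCG were the deeper ones on average (exact permutation p = 0.035). A few abundant transcripts are argued against, since -12017 remained without the 438 transcripts among the 100 most abundant of any library (exact permutation p = 0.015). Breakage that spares short transcripts stays open: the log2 ratio of the longest to the shortest transcripts moved by 0.225, against that explanation but within the spread (exact permutation p = 0.105), while the mean length weighted by counts fell from 3852 to 3426 bases (exact permutation p = 0.005), which goes with it. A response to hCG shared by both genotypes may account for it. The hCG changes of CTL and cKO correlated with r = 0.254, but the fall in detection itself enters that r, so it does not decide the question. Fewer starting molecules in the libraries after hCG would do the same and were not tested.

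Gained LRH-1 peaks lay at gained FAIRE peaks more often than persistent ones did. Weaker peaks among the gained are argued against, as the odds ratio within levels of fold enrichment was 4.1 against 3.32 overall. Peaks just under a list's threshold are argued against for the gained peaks, as the better-scoring FAIRE peaks with none of the other time within 500 bp gave an odds ratio of 3.77. For lost LRH-1 peaks at lost FAIRE peaks the same restriction gave 1.35 against 1.69 without it, and restricting the LRH-1 peaks instead gave 1.82. A part played by the threshold stays open for the lost peaks. Recovery of open chromatin by the LRH-1 assay itself could contribute: after hCG 23.7% of the best-scoring 2279 FAIRE peaks held a LRH-1 peak and 8.68% of the worst-scoring 2280, a ratio of 2.73. A change of LRH-1 binding with chromatin opening after hCG stays open beside it.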

How the results depend on the processing

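The fits without or with a term for the 3 libraries that stand apart, the mean CPM filter and the robust fit were chosen after seeing the data, as was the detection result; the other alternatives were set before the data were examined. All 20 alternatives of the 6 peak results kept direction and side of the threshold. The least firm was the loss of LRH-1 at lost FAIRE peaks, whose odds ratio was 1.23 in the better-scoring peaks (27% against 23.2%, Fisher's exact p = 0.0213). All 14 alternatives of detected transcripts did too, from -9850 with at least 10 reads to -13986.

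The counts of called transcripts did not hold, in the order cKO against CTL before hCG, the same after hCG, hCG in CTL, hCG in cKO and the interaction where all 5 are given (main counts 2, 3, 2, 0 and 11). DESeq2 called 1028, 3877, 3099, 4137 and 3493; limma on log2(TPM + 1) called 0 in all 5, with 1792, 1133, 2172, 3266 and 1348 at an unadjusted p under 0.05. With a mean CPM of at least 10 all 5 counts were 0. The robust fit gave 0, 0, 0, 0 and 2. Without the 3 libraries that stand apart the counts were 1, 0, 1, 0 and 7, and with a term for them 2, 5, 11, 12 and 8. Without a filter they were 0, 1, 0, 1 and 8, and with effective length as an offset 4, 4, 4, 3 and 7. Fits on the 2 groups alone gave 4, 0, 7 and 1, and size factors of the DESeq2 type gave 1, 2, 3, 0 and 9. The fold threshold and the filter on CPM of at least 1 changed no count. Leaving out 1 library gave 0 to 2, 0 to 7, 0 to 5, 0 to 1 and 1 to 13. For the interaction the counts were 7, 3 and 5 without CTL replicate 1, 2 and 3 before hCG, 4, 13 and 12 without those after it, 5, 5 and 1 without the cKO replicates before hCG and 9, 5 and 4 without those after it. In all of these the cause was not tested, except that fewer transcripts or libraries entered some fits.

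With the replicate number as a block the counts were 1, 4, 7, 8 and 11, sharing 1, 0, 2, 0 and 5 transcripts with the main calls. The numbers are shared only as numbers: 7 of 18 pairs with the same number had deviations correlated above 0.1, and 9 of 12 libraries correlated best with a library of their own number, a hint from the data and not the design. The highest r between libraries, 0.516 and 0.514, joined CTL and cKO before hCG at replicates 3 and 1. The 3 libraries that stand apart are all replicate 1. The permutation tests took no account of the number, so a batch that follows it is not excluded.

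Tests on gene lists, on motifs and on genes near LRH-1 peaks, with their alternatives, were not run, as gene names for these transcripts and an mm9 sequence and annotation were not used here. For covering at least 50% of each peak, 100 shifts were drawn. At the depth of these libraries, edgeR recovered at least 95.1% of simulated 16-fold changes at a coefficient of variation of 0.4. At the spread found here it called no simulated 64-fold change, so spread and not depth limited edgeR in those tables. Regrouping the real libraries gave interaction calls that the simulated tables did not, so those tables do not measure the power of the RNA tests.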

Other observations

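The test of FAIRE peaks near gained LRH-1 peaks was chosen after related results were seen; the test on better-scoring FAIRE peaks was set out before its result.

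FAIRE peaks seen only before hCG outnumbered those seen only after it where LRH-1 peaks were in both lists. Of the FAIRE peaks seen only before hCG, 846 of 9910 (8.54%, 95% interval 7.99 to 9.1) overlapped LRH-1 peaks in both lists, against 313 of 11256 FAIRE peaks seen only after hCG (2.78%, 95% interval 2.48 to 3.1). The ratio of before-only to after-only FAIRE peaks was 2.7 at these sites and 0.836 at FAIRE peaks without LRH-1 (odds ratio 3.23, Fisher's exact p = 3.23e-75, two-sided). With only the better-scoring FAIRE peaks and none of the other time within 500 bp, the odds ratio was 4.66, so FAIRE peaks just under a list's threshold are argued against. The LRH-1 lists were not restricted in this test. Sites in both LRH-1 lists needed a peak in the shorter list, that before hCG (5886 peaks against 9413). In the FAIRE list before hCG, 19.8% of the best-scoring 2143 peaks, 24.7% of the next best-scoring 2143 and 7.88% of the worst-scoring 2144 held a LRH-1 peak. Recovery of open chromatin by the LRH-1 assay could therefore contribute to this excess, although the share did not rise up to the best-scoring peaks. That, closing of chromatin at bound sites and a difference between ovarian tissue in the ChIP and granulosa cells in FAIRE were not told apart. Each assay has 1 list per time without replicates. The 3 best-scoring FAIRE peaks lost after hCG, on chromosome 13 and chromosome 1, all overlapped LRH-1 peaks of both times. They do not stand for the rest: 8093 of the 9910 FAIRE peaks seen only before hCG (81.7%) overlapped no LRH-1 peak of either list.

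LRH-1 peaks gained away from any FAIRE peak were tested for nearby opening. Of the 2844 such peaks, 560 (19.7%) had a FAIRE peak seen only after hCG within 10 kb and 452 (15.9%) one seen only before hCG, against 302 (22.1%) and 259 (18.9%) of 1368 persistent LRH-1 peaks without a FAIRE peak. Among peaks with only 1 of the kinds within 10 kb, 455 gained peaks were near an after-only and 347 near a before-only FAIRE peak, against 239 and 196 persistent ones. The odds ratio on these was 1.08 (95% interval 0.844 to 1.37, Fisher's exact p = 0.549). No opening near these sites beyond that near persistent ones was found, and an excess within this interval stays possible. Within 50 kb, counted the same way, it was 1.14 (95% interval 0.937 to 1.38).

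Transcripts with whole estimated counts in all 12 libraries (within 1e-06) were more alike between replicates than others of like abundance. Across 762 of them with a mean of at least 10 CPM, r within groups had a median of 0.48, against 0.31 for 685 others matched on mean CPM, and it was higher in 12 of 12 pairs.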
